A study of Mus musculus with 64 samples.

How the data were processed

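RNA was extracted from mouse liver with a column kit after bead beating, and about 5 µg of total RNA was labelled with 33P-dCTP by reverse transcription, per the labels' protocols. The labelled cDNA was hybridised to membranes named mouse17K-A and mouse17K-B, per the labels. The deposited values are z-scores (unit: score), by their own shape: every array has a mean of 0 and an SD of 1. The authors' image reading, background treatment, the transform before scaling and any filter are not given in the sources used here, and a log is only inferred from the shape. The design written before the data were examined assumed log2 values and said that z-scores would be used as deposited, which was done. An offset before the log, listed there for linear values, was not run.

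Mice were grouped by the sex and age in days in the labels into 4 age classes and both sexes, 8 groups in all, and the 2 arrays of a mouse were joined through its number in the title. Replicate numbers follow the order of the records and pair no mice. Among adults, 5 males and 5 females share an age in days and have neighbouring title numbers. The deviations from the group means of these 5 pairs had an r of 0.194 to 0.729. Among the other pairs of an adult male and female, a share of 0.345 had an r over 0.1. The description of male old replicate 2 names another mouse than its title does; the title, age and sex were used. A probe was given a gene only where the platform's annotation lists 1 symbol, with symbols updated by gene number through the RefSeq table of GRCm38.p6. Of 16896 probes 9663 had 1 gene (9641 matched by gene number), 436 had several and 6797 had none, which leaves 7151 genes, 1858 of them with several probes. All columns of the tables were used.

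Probes were fitted on each membrane separately with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, over all 32 mice with 8 group means, so that all groups share an estimate of the spread. The slope used age in days and sex, and the comparison among juveniles used age class, with the juveniles parted at 21 days, and sex. P-values were adjusted by Benjamini-Hochberg over the probes of both membranes within each of the 10 comparisons, with a threshold of 0.05. Age comparisons average the sexes, and the adult sex comparison averages the adult classes.

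A total of 36 lists of genes (pathways, liver functions, markers of other cell types) was fixed before the data were examined, from textbook knowledge. They hold 1496 symbols, of which 654 were measured, and the 32 lists with 5 or more measured genes were tested in 3 comparisons. Each gene had 1 value, the mean of its probes. The tests were camera at a preset correlation of 0.01, camera with an estimated correlation and fry, adjusted over the lists within a comparison. Members were also adjusted over the list alone. The mean of a list against all genes was tested by 100000 permutations of the mice within sex (within age class for sex), two-sided. In the text "rose" is used of a list past camera's threshold.

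The rule for named genes, written before the data were examined, took the largest changes past the threshold, and where none passed the 5 genes with the smallest p, given as values. It added, for each list past camera, the 4 members with the smallest p in the fit of single probes, and Xist, Ddx3y, Eif2s3y, Kdm5d and Uty where measured.

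The scripts were tested on simulated data with the real spread, with 50 probes changed at each of 4 sizes. All 4 sizes were present in the same simulation, and the larger shifts ease the adjusted threshold for the smaller ones. Recovery would be lower where few probes change, which was not simulated. Shifts of 0.25, 0.5, 1 and 2 array SD were recovered at 9.1, 55.3, 96.2 and 99.7% for young adult versus juvenile, 8.6, 52.6, 95.6 and 99% for old versus young adult and 17.3, 68.6, 97.6 and 99.8% for adult females versus males (mean of 20 simulations over 16896 probes, with 2.9, 1.9 and 4.9 false calls).

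Alternatives were quantile normalisation, centring on the median with scaling to the same median absolute deviation, leaving out the dimmest probes by mean signal, eBayes with trend and robust, arrayWeights (with statmod 1.5.0), adjustment within a membrane, the 5 title-number sets as a block, an animal number under 100 as a term in adults, leaving out juveniles of 17 to 21 days, log2 of age, adults only, leaving out the old male with the differing description, and leaving out each of the 32 mice. For the lists they were the other tests, the brightest probe of a gene and each membrane alone. Added after the data were seen were the first 2 principal components as covariates, leaving out 6 mice whose arrays stand apart, subtracting from each probe the mean deviation of the probes 22, 44, 66 and 88 positions before and after it, those 5 pairs of adults with and without a block, and for the lists both scalings and an estimated correlation in each setting where a further list passed. Plots were drawn with matplotlib 3.10.9.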

Results

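Gene expression was measured in the liver of 32 C57BL/6 mice, an inbred laboratory strain, fed without restriction. Each mouse gave RNA for 2 nylon membranes, called A and B, which carry 8448 cDNA probes each, so the data are 64 arrays and 16896 probes. By the ages in the labels, 8 mice were juvenile (17 to 44 days, 4 male and 4 female) and 9 were young adult (174 to 194 days, 5 male and 4 female). A further 7 were middle-aged (479 to 499 days, 3 male and 4 female) and 8 were old (712 to 743 days, 4 male and 4 female). The deposited values are z-scores within an array, so every difference is given in array standard deviations (array SD), and a fold change cannot be had from them. No signal over background was given in the values.

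Probes of 5 genes that hepatocytes express strongly, picked from textbook knowledge, lay high on membrane A. Alb, which encodes serum albumin, had a level of 3.29 ± 0.242 array SD (SD, n = 32), at percentile 99.9 of the membrane. Apoa1, the main protein of high-density lipoprotein, was at 2.70 ± 0.270 (percentile 99.3). Ttr, the thyroxine carrier transthyretin, was at 1.80 ± 0.336 (percentile 95.7). The metal-binding protein gene Mt1 was at percentile 99.4. A probe for Gstm2, a glutathione transferase, lay at percentile 99.8 on membrane A, and another probe for Gstm2 lay at percentile 68.7 on membrane B. Over the 51 probes of membrane A named for hepatocyte genes the mean level percentile was 56.8, against 47.6 for random named probes (one-sided permutation p = 0.0096). Over the 46 such probes of membrane B it was 53.4 against 48.3 (permutation p = 0.103). Ribosomal protein genes lay at mean percentiles 61.3 (A, 47 probes, permutation p = 0.00039) and 58.0 (B, 96 probes, permutation p = 0.00018). Respiratory chain genes lay at 52.2 (A, permutation p = 0.194) and 52.7 (B, permutation p = 0.13). Genes of muscle, pancreas, blood cells and fat lay at 66.1 (A, 10 probes, permutation p = 0.0189) and 55.5 (B, 10 probes, permutation p = 0.204). Mean levels of probes 22 positions apart had r = 0.368 on A and 0.457 on B, so these permutations treat as independent probes that are not.

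Probes named for one gene seldom varied together, which bears on every gene named here. Across the 963 genes with probes on both membranes, the mean level on A and that on B had a correlation of r = 0.0397 (rho = 0.0352). For the difference between young adult and juvenile mice r was -0.00257, between old and young adult mice r = 0.0345 and between adult females and males r = -0.00729. These correlations are across genes, which are not independent replicates. Arrays of one membrane did share their pattern of levels, with a median correlation between arrays of 0.915 on A (0.420 to 0.977) and 0.940 on B (0.627 to 0.986), and no array was identical to another. The probes of some genes moved together over the mice. Scp2, the sterol carrier, had a mean r of 0.769 between its 3 probes with the first 2 principal components removed. The value was 0.742 between the 5 probes of Ppia, cyclophilin A. Rplp0, a ribosomal stalk protein, had 0.736 between 4 probes and Ftl1, ferritin light chain, 0.692 between 5. The 7 probes of H19, an imprinted RNA of fetal liver, had a mean r of 0.0636. Over the 1858 genes with several probes the median was 0.0220, against 0.00361 for random pairs.

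Probes at certain distances in the order of the probe numbers varied together more than probes of one gene did. Deviations from the group means of probes 22 positions apart had a mean correlation over the mice of 0.417 on A and 0.430 on B, and those 11 positions apart 0.0321 and 0.0107. The 126 pairs of probes of one gene that lay 22, 44, 66 or 88 positions apart had a median r of 0.662, and the other 3327 pairs one of 0.0628. The values of single genes given above were not parted by this distance.

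**Figure D1:**
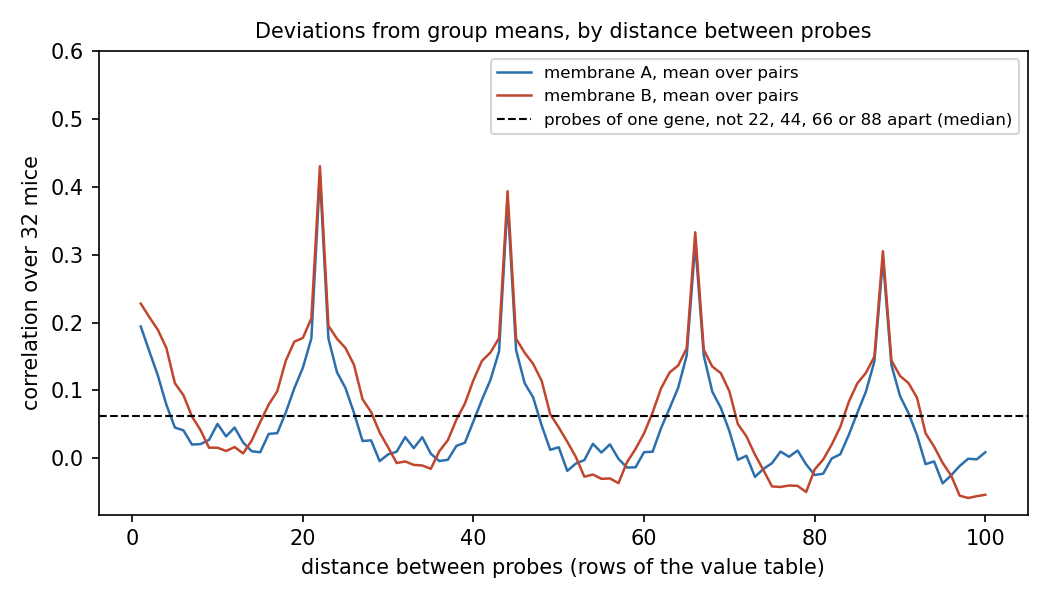
Mean correlation over the 32 mice (vertical axis) between deviations from group means of probes, by their distance in positions of the value table (horizontal axis), for membrane A (blue) and B (red), with the median for pairs of probes of one gene that do not lie 22, 44, 66 or 88 positions apart as a dashed line. At 22 positions the correlation is 0.417 on A and 0.430 on B, and the dashed line lies at 0.0628.

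Probes for sex-linked genes did not separate the sexes. Xist, the RNA that silences an X chromosome in females, read -0.864 ± 0.173 in 12 adult females and -0.760 ± 0.109 in 12 adult males (SD). The Y-linked genes Eif2s3y (-0.632 ± 0.187 in females, -0.612 ± 0.278 in males) and Uty (-1.12 ± 0.283 and -1.05 ± 0.247) were at like levels in both sexes, all 3 with an adjusted p of 1.00. The labels of sex therefore had no check in these values, and Ddx3y and Kdm5d were not among the annotated probes used here. Xist acts in females and the Y-linked genes exist in males alone, so the probes, their names or the labels missed that difference. Comparisons of the sexes in other genes and lists thus had no working control here.

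A component found on both membranes separated some mice from the rest. The first principal component held 37.7% of the variance, and its values on membranes A and B went together over the 32 mice (r = 0.954, rho = 0.936, both permutation p = 1e-05, the smallest these permutations can give, and r = 0.942 without the 2 mice farthest from the median). It lay between 25.7 and 47.0 in male and female old replicate 2, female juvenile replicate 2 and male and female young adult replicate 3, whose titles carry the running numbers 27 to 34. Female juvenile replicate 3, with the number 43, lay nearly as high (24.3). It was -73.1 in male juvenile replicate 2. The 8 groups explained 25.2% of it (permutation p = 0.371) and the 5 sets of title numbers within which the ages recur 4.89%. The second component held 11.5% of the variance, and the same sets explained 80.7% of it (permutation p = 1e-05, again the smallest possible).

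The first comparison, of young adult with juvenile mice, asks how the liver differs between the weeks around weaning and adulthood. Genes of the mitochondrial respiratory chain, which makes most of the cell's ATP, rose together as a list in young adults: 45 of its 60 measured genes lay above 0 and 15 below, with a mean difference of 0.0501 array SD (camera with a preset correlation, adjusted p = 0.000305). With an estimated correlation the adjusted p = 0.93, so the call is lost. The list mean per mouse, taken against all genes, was 0.159 ± 0.0449 in 9 young adults and 0.107 ± 0.0476 in 8 juveniles (SD), with 7 of the 9 young adults above the juvenile mean. Genes of fatty acid oxidation, the breakdown of fat in mitochondria and peroxisomes, also rose as a list, with 22 of 27 above 0 and a mean of 0.0559 (adjusted p = 0.0306, and adjusted p = 0.93 with an estimated correlation). Their list mean was 0.0345 ± 0.0490 in young adults and -0.0233 ± 0.0962 in juveniles, and 8 of 9 young adults were above the juvenile mean. This rests in part on male juvenile replicate 2 (-0.229): without it the juvenile mean was 0.00608, 6 of 9 young adults lay above it, the difference was 0.0284 in place of 0.0577 and the adjusted p was 0.572. The call was also lost without female juvenile replicate 1 (0.217), female young adult replicates 2 (0.236) and 4 (0.166) or male young adult replicates 3 (0.0543) and 5 (0.0651). Permuting the mice within each sex gave a two-sided permutation p of 0.0393 (adjusted 0.728) for the respiratory chain and 0.101 (adjusted 0.808) for fatty acid oxidation, and fry gave an adjusted p of 0.983 for both.

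No single member of either list passed, and 0 genes of any list passed when adjusted over the list alone or over all 7151 genes. In the respiratory chain, Atp5o, a subunit of ATP synthase, differed by 0.188 ± 0.0832 (SE) and the complex I subunit Ndufb11 by 0.235 ± 0.106. The catalytic ATP synthase subunit Atp5b differed by 0.232 ± 0.112 and the cytochrome c oxidase subunit Cox6a1 by 0.121 ± 0.0615. Each had an adjusted p of 1, with 7, 9, 8 and 8 of 9 young adults above the juvenile mean. Not all members lay above 0: by gene means Uqcrh, a subunit of complex III, was at -0.171 ± 0.0832 (adjusted p = 1). In fatty acid oxidation, Etfa, which passes electrons to the respiratory chain, differed by 0.182 ± 0.0880 and Hadh by 0.199 ± 0.102. The medium-chain dehydrogenase Acadm differed by 0.205 ± 0.124 and the peroxisomal enzyme Hsd17b4 by 0.158 ± 0.0991. For each of these 4 genes 8 of 9 young adults were above the juvenile mean and the adjusted p was 1. Both list calls come from membrane B, where the adjusted p was 2.48e-05 and 0.0149, and membrane A alone gave 0.907 for each. Without the 6 mice that stand apart on the first component the adjusted p was 0.0781 for the respiratory chain and 0.421 for fatty acid oxidation, whose call quantile normalisation ended too (0.199). Over the alternatives it ranged from 7.62e-06 to 0.983 and from 0.00545 to 0.983.

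The other 30 tested lists did not pass between young adults and juveniles. Circadian clock genes came closest, with 10 of 15 below 0 and a mean of -0.0691 (adjusted p = 0.0662, and 0.468 with an estimated correlation). They passed with the title-number sets as a block (0.0227, in a range of 0.0227 to 0.983 over the alternatives), and without male young adult replicate 2 (0.0462) or 3 (0.047), female young adult replicate 3 (0.0196), female juvenile replicate 3 (0.0409) or male juvenile replicate 4 (0.0442). In each of these 6 settings the call was lost with an estimated correlation (adjusted p of 0.137 to 0.38). Among the circadian genes were the clock activator Arntl at -0.117 ± 0.0587 (SE) and its partner Npas2 at -0.258 ± 0.148. Of 17 genes of fetal and juvenile liver 12 lay below 0, with a mean of -0.0114 (adjusted p = 0.813). The imprinted genes Peg3 at -0.0955 ± 0.0554 and H19 at -0.0458 ± 0.0525 were among them. Of 61 cell cycle genes 31 lay above 0 (0.813). Above 0 were 11 of 19 genes of xenobiotic metabolism (0.667), 7 of 10 of bile acid synthesis and transport (0.757) and 8 of 14 plasma proteins of hepatocytes (0.813). So were 14 of 25 of amino acid and urea metabolism and gluconeogenesis (0.813), 6 of 14 of cholesterol synthesis (0.813), 8 of 16 of fatty acid synthesis (0.813) and 34 of 63 ribosomal protein genes (0.813). Among stress and turnover lists, 15 of 29 heat shock genes, 17 of 27 of the endoplasmic reticulum stress response, 4 of 12 of the p53 and senescence list, 17 of 30 antioxidant and metal genes, 21 of 33 of the proteasome (each 0.813) and 5 of 14 immediate early genes (0.963) were above 0.

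Markers of other cells the tissue could hold did not pass either. Above 0 in young adults were 5 of 16 macrophage, 5 of 6 granulocyte, 12 of 17 erythroid and blood, 5 of 12 endothelial, 8 of 15 stellate cell and fibroblast genes (each adjusted p = 0.813). So were 7 of 20 cholangiocyte, 22 of 40 extracellular matrix, 6 of 15 interferon response and 5 of 11 acute phase and complement genes (each adjusted p = 0.813), 4 of 8 antigen presentation genes (0.963) and 1 of 5 adipose genes (0.948). Female-biased (1 of 5) and male-biased liver genes (3 of 7) and sex chromosome genes (2 of 7) had adjusted p = 0.813, 0.813 and 0.757. The mean, the median and camera's direction did not all share a sign for the male-biased, cell cycle, extracellular matrix, antigen presentation, fatty acid synthesis, plasma protein, heat shock, p53 and proteasome lists. B and plasma cell, T and NK cell, exocrine pancreas and skeletal muscle lists had 2, 1, 1 and 4 measured genes and were not tested.

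Gene by gene, limma called 0 of 16896 probes between young adults and juveniles. At an unadjusted p under 0.05 there were 277 probes, 95 higher and 182 lower, where chance gives 845, and 233 to 553 with a mouse left out (highest without male juvenile replicate 3). The 5 genes with the smallest p included Rab33b, a small GTPase of the Golgi, at -0.924 ± 0.253 (SE), the transcription factor Bach2 at -0.403 ± 0.124 and the Golgi protein gene Blzf1 at -0.497 ± 0.160. The others were Echs1, a mitochondrial enzyme of fatty acid oxidation, at 0.396 ± 0.128, and Btbd18 at -1.34 ± 0.463. Each had an adjusted p of 1, with 9 of 9 young adults on the same side of the juvenile mean, and 7 of 9 for Btbd18. Other probes had the other sign for Bach2 (0.010) and Blzf1 (0.0733 and 0.0830). The 2 largest of these differences come from probes far below the array mean. Rab33b read -2.95 ± 0.888 (SD) in young adults and -1.99 ± 0.517 in juveniles, and Btbd18 -3.74 ± 1.22 and -2.455 ± 0.947. The median SE was 0.118, and for 99.0% of probes the 95% interval of the difference lay within 1 array SD of 0. Leaving out the juveniles of 17 to 21 days called 1 probe, at -1.46 ± 0.147 (adjusted p = 6.58e-06). It is 1 of 2 probes of Fbxl6, an F-box protein of the ubiquitin system, and the other was not called. The called probe read 1.94 and 1.66 in the females of 40 and 33 days and -1.29 to -0.29 in the other juveniles (chosen after its values were seen).

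**Figure D2:**
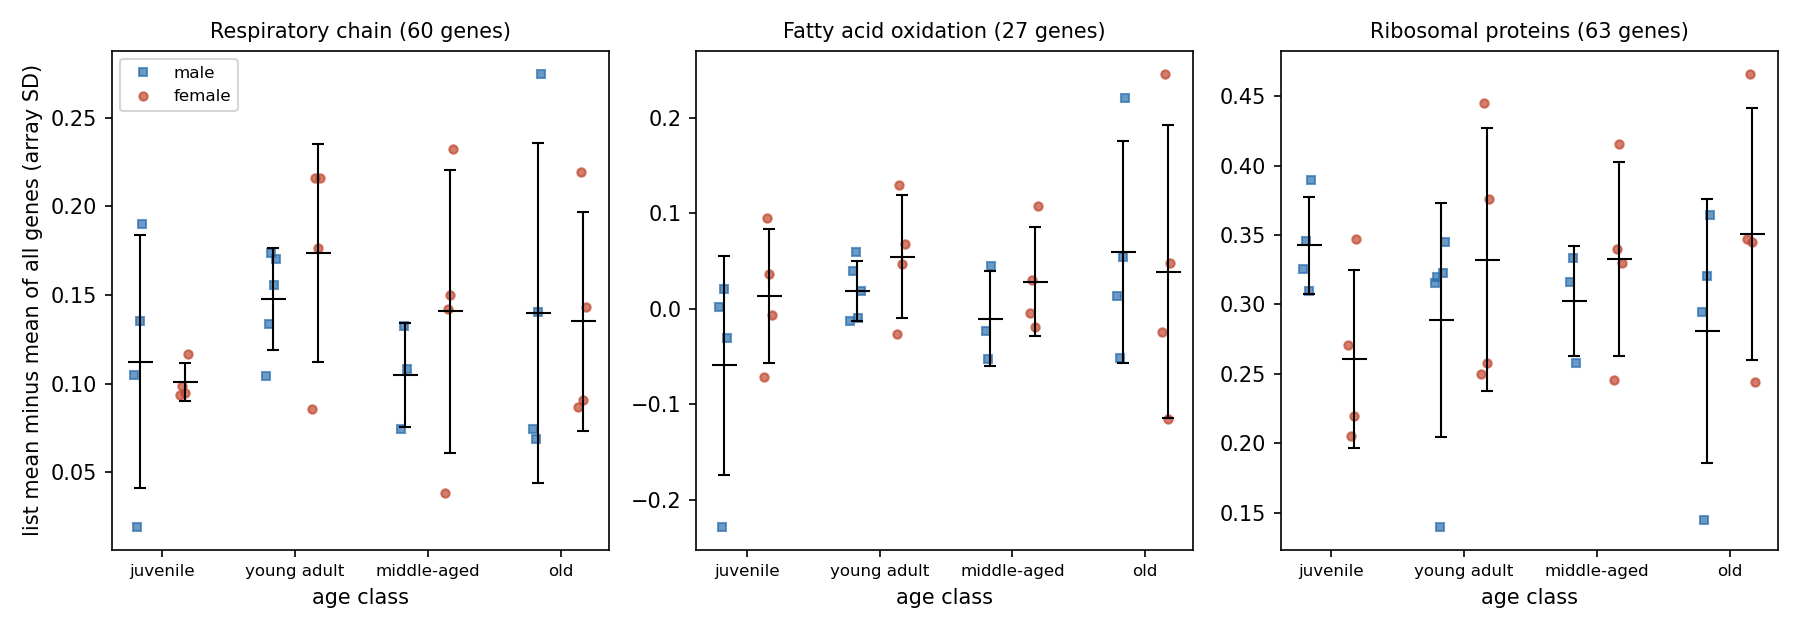
Mean of each list minus the mean of all genes in array SD (vertical axis) by age class (horizontal axis) for the 60 respiratory chain, 27 fatty acid oxidation and 63 ribosomal protein genes, each point a mouse (squares male, circles female), with group means and SD in black. Young adults average 0.159 against 0.107 in juveniles for the respiratory chain, and adult females 0.339 against 0.290 in adult males for ribosomal proteins.

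The comparison of old with young adult mice asks what differs in the liver with adult age. No list passed. Plasma proteins made by hepatocytes lay above 0 in old mice for 11 of 14 genes, with a mean of 0.0685 (adjusted p = 0.344). Among them were Igfbp4, a binding protein of insulin-like growth factors, at 0.203 ± 0.0962 (SE), Apob, the protein of very-low-density lipoprotein, at 0.263 ± 0.160, and Apoa4 at 0.198 ± 0.124. Acute phase and complement genes lay above 0 for 9 of 11, with a mean of 0.0793 (0.344). The complement proteases C1s1 and C1ra were at 0.351 ± 0.155 and 0.108 ± 0.0623, and Socs3, a brake on cytokine signalling, at -0.198 ± 0.0920. Extracellular matrix genes lay below 0 for 27 of 40 (mean -0.0557, adjusted p = 0.663), with the collagens Col5a1 at -0.334 ± 0.130 and Col14a1 at -0.233 ± 0.0933. Respiratory chain genes lay below 0 for 42 of 60 (mean -0.0402, adjusted p = 0.816) and proteasome genes for 23 of 33 (0.952). Antigen presentation genes lay above 0 for 6 of 8 (0.816), and macrophage, interferon and cell cycle lists had 6 of 16 (0.957), 7 of 15 (0.877) and 26 of 61 (0.952) above 0.

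For the old against young adult lists, the smallest adjusted p was 0.967 with an estimated correlation, 0.969 with fry and 0.815 by permutation of the mice, and 0 genes passed adjusted over the list alone or over all genes. The smallest adjusted p within a list was 0.0553, for Muc1, an epithelial mucin of the cholangiocyte list, at -0.383 ± 0.117. The mean, median and camera's direction differed in sign for the male-biased, sex chromosome, fetal, macrophage, interferon, ribosomal protein, fatty acid oxidation, heat shock, circadian, erythroid, granulocyte, endothelial and adipose lists. Leaving out male old replicate 2, whose description names another mouse than its title does, brought the plasma protein list to an adjusted p of 0.0216, in a range of 0.0216 to 0.984 over the mice left out, and with an estimated correlation the adjusted p without that mouse was 0.904.

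By limma 0 probes passed between old and young adult mice, and 1042 had an unadjusted p under 0.05 (486 higher and 556 lower in old mice, 845 by chance). Leaving out 1 mouse gave 502 (male old replicate 2) to 2174 (female old replicate 3), and 7 of the 32 mice moved the count by over 1.5 times. Ski, a repressor of signalling by TGF-beta, was at -1.36 ± 0.307 (SD) in 8 old and -1.83 ± 0.137 in 9 young adult mice, a difference of 0.472 ± 0.115 (SE). Slc25a32, a mitochondrial carrier, differed by 0.321 ± 0.0849 and Sem1, a small proteasome subunit, by 0.221 ± 0.0589. Caprin1, an RNA-binding protein of stress granules, differed by 0.328 ± 0.0894 and Ptprz1, a receptor phosphatase, by 0.261 ± 0.0715. All 5 had an adjusted p of 0.685, with 8 of 8 old mice above the young adult mean. Another probe of Sem1 had the other sign (-0.0523). The median SE was 0.118.

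Within adult life, middle-aged and young adult mice had 0 calls by limma, and 86 probes had an unadjusted p under 0.05 (leaving out female young adult replicate 1 moved this up by over 1.5 times, and no other mouse did). The genes with the smallest p were Ppp6c, the catalytic subunit of a protein phosphatase, at -0.421 ± 0.120 (SE), Cops8 of the COP9 signalosome at -0.408 ± 0.120, Tmem39b at -0.352 ± 0.109, Ptprz1 at 0.216 ± 0.0746 and Cdca7 at -0.293 ± 0.102. Each had an adjusted p of 1, with 7 of 7 middle-aged mice on that side of the young adult mean (6 of 7 for Cdca7). Old and middle-aged mice also had 0 calls, with 1012 probes at an unadjusted p under 0.05 (547 without male middle-aged replicate 2 to 2011 without female old replicate 3). Ski was again at the front (0.526 ± 0.123), but with the same 8 old mice as against young adults, so this is no independent observation. It was followed by Cxadr, the coxsackievirus and adenovirus receptor, at -0.302 ± 0.0785, and the Wnt pathway regulator Apc at -0.436 ± 0.118. Edem2 of endoplasmic reticulum quality control was at -0.372 ± 0.104 and Ppp2r5c, a regulatory subunit of a protein phosphatase, at -0.377 ± 0.106, all 5 with an adjusted p of 0.653 and 8 of 8 old mice on that side of the middle-aged mean. Other probes had the other sign for Cxadr (0.0838 and 0.190), Apc (0.0871) and Ppp2r5c (0.130). With arrayWeights, whose iterations stopped before convergence, 2 and 12 probes passed in these comparisons. Among the 12 were Ski (adjusted p = 0.0278, in a range of 0.0278 to 0.999 over its alternatives) and Apc (0.0282, in a range of 0.0282 to 0.999), and among the 2 was Dis3, a subunit of the RNA exosome (-0.304 ± 0.0545, adjusted p = 0.0468, against 1 without weights).

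Over the whole range of ages, limma called 0 probes for a linear slope with age, and 1576 had an unadjusted p under 0.05 (884 slopes above 0 and 692 below, 845 by chance). With scaling to the median absolute deviation 579 lay above 0 and 1363 below, so the side of the majority depends on the scaling. Leaving out 1 mouse gave 601 (female old replicate 2) to 3433 (female juvenile replicate 2), and 9 of the 32 mice moved the count by over 1.5 times. Per 100 days, Sem1 had a slope of 0.0297 ± 0.00800 array SD (SE), Thoc2, of the complex that exports mRNA, 0.0540 ± 0.0160 and Oosp1 -0.0587 ± 0.0175. Gtf2h3, a subunit of transcription factor TFIIH, had -0.0371 ± 0.0111 and Zfp638 0.0474 ± 0.0145, and all 5 an adjusted p of 0.481. Other probes of Sem1 (-0.00363), Thoc2 (-0.0161) and Zfp638 (-0.0186) had the other sign. The sign of Gtf2h3 turned when the deviation of neighbouring probes was subtracted.

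The comparison of adult females with adult males asks how the sexes differ once grown. Ribosomal protein genes, which encode the protein part of the ribosome, rose as a list in females, with 51 of 63 above 0 and a mean difference of 0.0442 array SD (camera, adjusted p = 2.5e-05). With an estimated correlation the adjusted p = 0.88, fry gave 0.973, and the two-sided permutation of the mice gave p = 0.149 (adjusted 0.925). The list mean was 0.339 ± 0.0781 in 12 females and 0.290 ± 0.0735 in 12 males (SD), with 8 of 12 females above the male mean. Rps29 differed by 0.158 ± 0.0717 (SE) between females and males, Rpl7a by 0.124 ± 0.0595, Rps25 by 0.150 ± 0.0731 and Rpl5 by 0.166 ± 0.0816, with 9, 10, 10 and 10 of 12 females above the male mean and an adjusted p of 1.00 for each. Without the 6 mice that stand apart on the first component the adjusted p of the list was 0.994, in a range of 6.3e-06 to 0.994 over the alternatives.

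Genes of bile acid synthesis and transport lay above 0 in females for 8 of 10 (mean 0.0791, adjusted p = 0.0607, estimated 0.88), with the sterol hydroxylase Cyp7b1 at 0.146 ± 0.106 (SE) and Scp2 at 0.124 ± 0.0987. Xenobiotic metabolism genes lay above 0 for 16 of 19 (adjusted p = 0.183), with the glutathione transferases Mgst1 at 0.176 ± 0.0865 and Gstp1 at 0.227 ± 0.163. Above 0 were also fatty acid oxidation genes for 20 of 27 (0.63) and respiratory chain genes for 36 of 60 (0.398). Genes known for higher expression in female liver lay below 0 in females for 4 of 5 (mean -0.0625, adjusted p = 0.63). Genes known for higher expression in male liver lay above 0 for 4 of 7 (mean 0.0762, adjusted p = 0.63), Cyp7b1 and Gstp1 among them. Sex chromosome genes lay below 0 for 6 of 7 (0.63). Macrophage, erythroid and blood, endothelial and cholangiocyte markers lay above 0 for 7 of 16 (0.807), 12 of 17 (0.63), 5 of 12 (0.958) and 8 of 20 (0.753). No list other than the ribosomal one passed in the design set beforehand, and 0 genes passed adjusted over the list alone or over all genes. The mean, median and camera's direction differed in sign for the cell cycle, extracellular matrix, macrophage, heat shock, endoplasmic reticulum stress, p53, circadian, adipose and immediate early lists.

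Some of these lists passed camera with the preset correlation between adult females and males under other settings, and with an estimated correlation each of these 22 calls was lost. Bile acid genes did with scaling to the median absolute deviation (adjusted p = 0.0437, in a range of 0.0437 to 0.973 over the alternatives). They also did without any of 8 mice: female young adult replicate 1 (0.0255), female middle-aged replicates 1 (0.041) and 2 (0.0424), male young adult replicates 2 (0.0481) and 3 (0.0133), female old replicate 3 (0.0112), male middle-aged replicate 3 (0.00725) and male old replicate 4 (0.0154), and with an estimated correlation the adjusted p was 0.466 to 0.908 in these 9 settings. Xenobiotic metabolism passed without female middle-aged replicate 1 (0.0449) or male old replicate 4 (0.00669), and fatty acid oxidation without the latter (0.0379), against an adjusted p of 0.737, 0.466 and 0.571 with an estimated correlation. The respiratory chain passed without female young adult replicate 1 (0.0333), female middle-aged replicate 1 (0.041) or male old replicate 4 (0.00939), against an adjusted p of 0.809, 0.737 and 0.466 with an estimated correlation. Amino acid and urea metabolism and gluconeogenesis passed on membrane A alone (0.0486, in a range of 0.0486 to 0.994) and without female young adult replicate 1 (0.0255) or male old replicate 4 (0.00669), against an adjusted p of 0.94, 0.809 and 0.466 with an estimated correlation. Among 10 adults that form 5 pairs of a male and a female of the same age with neighbouring title numbers, fatty acid oxidation passed with the pairs as a block (0.0229) and without it (0.0169, in a range of 0.0169 to 0.994 over the alternatives). Acute phase and complement genes, 8 of 11 of them above 0 with all mice (0.683), did so at the same values, and for both lists the adjusted p with an estimated correlation was 0.991 with the block and 0.986 without it.

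Limma called 0 probes between adult females and males, and 199 had an unadjusted p under 0.05 (115 higher and 84 lower in females, and 141 to 362 with a mouse left out, highest without female old replicate 3). With scaling to the median absolute deviation 77 were higher and 88 lower. Kctd12, an auxiliary subunit of GABA-B receptors, differed by -0.216 ± 0.0631 (SE), Tvp23b by 0.310 ± 0.0978 and Zc3h6 by -0.510 ± 0.166. The tetraspanin gene Tspan3 differed by 0.171 ± 0.0558 and D16Ertd472e by -0.287 ± 0.0992. Each of the 5 had an adjusted p of 1.00, with 12, 11, 12, 11 and 10 of 12 females on that side of the male mean. Another probe of Zc3h6 had the other sign (0.0569). The median SE was 0.0999.

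In juveniles, females and males had 0 calls by limma and 1730 probes at an unadjusted p under 0.05 (1047 higher and 683 lower in females). The females were 19, 21, 33 and 40 days old and the males 17, 40, 43 and 44 days. The comparison had no term for age within the class, so sex is partly mixed with age around weaning. With scaling to the median absolute deviation there were 2771, 953 higher and 1818 lower, so the side of the majority depends on the scaling. Leaving out 1 mouse gave 355 (male juvenile replicate 2) to 3697 (female juvenile replicate 4). Tmem147 was at -0.818 ± 0.164 (SD) in 4 females and -0.345 ± 0.0443 in 4 males. Mettl6, a methyltransferase of tRNA, differed by -1.50 ± 0.399 (SE) and Irf8, a transcription factor of macrophages and dendritic cells, by 0.770 ± 0.214. Purb differed by -1.03 ± 0.286 and Cuta by 0.513 ± 0.144, and all 5 had an adjusted p of 0.422, with 4 of 4 females on that side of the male mean. Another probe of Purb had the other sign (0.0400). The probes of Mettl6 and Purb lay below the array mean. Mettl6 read -3.08 ± 0.409 (SD) in females and -1.58 ± 0.909 in males, and Purb -2.11 ± 0.321 and -1.09 ± 0.932. With arrayWeights 949 probes passed, in a range of 0 to 949 over the alternatives.

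The sex difference itself was compared between ages. Between adults and juveniles 0 probes passed by limma and 757 had an unadjusted p under 0.05 (372 without male juvenile replicate 2 to 1761 without female juvenile replicate 4). The juvenile part of this comparison carries the same mixing of sex with age. At the front were Cuta (-0.605 ± 0.166, SE), the phosphatase gene Ppm1l (2.10 ± 0.595), Tmem147 (0.468 ± 0.134), Rab40c (-0.762 ± 0.221) and Krit1 (1.61 ± 0.488), each with an adjusted p of 0.687. Another probe of Rab40c had the other sign (0.221). Between old and young adult mice 0 passed by limma and 84 had an unadjusted p under 0.05 (71 to 292 with a mouse left out, highest without female old replicate 2). At the front were Sorbs2 (0.359 ± 0.119), 9930021J03Rik (2.42 ± 0.840), the primase subunit Prim2 (0.977 ± 0.344), Cox16 (-0.485 ± 0.175) and the imprinted RNA Kcnq1ot1 (0.611 ± 0.222), each with an adjusted p of 1. Another probe of Kcnq1ot1 had the other sign (-0.143). Between juveniles of 33 to 44 days (5 mice) and of 17 to 21 days (3 mice), around weaning, 0 passed by limma and 803 had an unadjusted p under 0.05 (360 without male juvenile replicate 2 to 2610 without female juvenile replicate 3). The copper transporter gene Slc31a1 differed by 0.566 ± 0.146, Prrg1 by 0.768 ± 0.203 and Rab3ip by 0.727 ± 0.194. Zfp945 differed by 1.61 ± 0.450 and Susd4 by 0.770 ± 0.226. Each had an adjusted p of 0.687, with 5 of 5 older juveniles above the mean of the younger ones. The median SE of these 3 comparisons was 0.198, 0.236 and 0.175.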

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

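Chosen after the result was seen were the tests with principal components, of the levels of hepatocyte genes, of neighbouring probes on the list calls and of the order of title numbers; the others were set before their result was seen. Bounds written for the tests with values of 0 and 0 calls, r = 0.0397, and permutation p of 0.0096, 0.103, 0.728 (adjusted) and 0.00014 below would have decided for or against an explanation, and these were left open after their values were seen, for the reasons given. So was the test of the title-number sets on the list calls, whose bound would have decided against the sets. A test of the noise of single probes, by the correlation between probes of a gene (median 0.0449), was written and dropped, since wrong names would give the same. In 217 group values tested for an outlying mouse, 8 had one, and chance flags about 1 in 20 groups, 11 here, so the number of these is no more than chance gives.

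Single mice far from the others of their group were these. Slc25a32 read -0.52 in female juvenile replicate 4, against -0.3 to -0.26 in the other juvenile females. In male juvenile replicate 2, which also lies at -73.1 on the first component, Ptprz1 read -0.7 against -0.5 to -0.48 and Atp5b 0.26 against 0.68 to 0.71. Etfa read 0.01 in female young adult replicate 1, against 0.55 to 0.59. In male young adult replicate 3 the ribosomal protein list mean was 0.14 against 0.316 to 0.345, Caprin1 read -0.36 against -0.73 to -0.65 and Ndufb11 0.57 against -0.43 to -0.3. Rab33b read -1.97 in male old replicate 1, against -2.46 to -2.43.

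No probe passed in any of the 10 comparisons. With the first 2 principal components as covariates 0 probes passed, and 0 passed with the deviation of neighbouring probes subtracted, but this argues against neither kind of variation. Simulated shifts of 0.25 array SD were recovered at 8.6 to 17.3% in 3 comparisons (of 1 array SD at 95.6 to 97.6%), with shifts of all sizes present together. In 5 comparisons arrayWeights, whose iterations stopped early, called 2, 12, 949, 14 and 21 probes. Whether names belong to their probes was not decided either, by the r of 0.0397 between the mean levels of 963 genes on A and B or by the levels of hepatocyte genes (permutation p = 0.0096 on A, with a sampling error of 0.000308, and 0.103 on B). Levels of different probes go with their position and need not share a scale, genes of other tissues lay as high (percentile 66.1 against 56.8 on A), ribosomal protein genes lay above random probes on B (permutation p = 0.00018), and a count of probes uses no names. Sex-linked genes bear on this too: Xist acts in females, and Eif2s3y and Uty lie on the Y chromosome. Between adult females and males they differed by -0.100 ± 0.0685, -0.0278 ± 0.0974 and -0.0618 ± 0.133 (SE). If the sex labels hold, an absent difference cannot be the reason for these 3 genes, and wrong names are among the reasons left. For the other probes, variation between arrays, position, and absent or small differences between the ages and sexes all stay open.

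The 3 lists that passed camera did so where members vary together more than the preset correlation allows: of 100 regroupings of the mice by age, 44 gave at least 1 list past the threshold, and 56 did by sex. The real grouping is counted among these. With the title-number sets as a block 3 of the 3 lists passed. The groups compared are spread nearly evenly over the sets, so the block could hardly change these differences and decides little on the sets. With the deviation of neighbouring probes subtracted the respiratory chain and ribosomal protein lists, 2 of 2, still passed. Their differences of 0.0539 ± 0.0299 and 0.0478 ± 0.0316 (SE) became 0.0437 ± 0.0212 and 0.0318 ± 0.0153, so a part of position stays open for them. The fatty acid oxidation list lost its call in that test (adjusted p = 0.284), its difference being 0.0597 ± 0.0441 (SE) before and 0.0320 ± 0.0294 after. This fall is smaller than the first SE, but both values come from the same mice and the error of the fall was not computed. A part of position therefore cannot be told apart. A difference between the age or sex groups had an adjusted permutation p of 0.728 at the smallest. This lies over the bound of 0.2 set beforehand to argue against such a difference. The bound was set aside after the values were seen, since the adjustment over 32 lists can put a small difference above it. The respiratory chain had an unadjusted permutation p of 0.0393, but camera picked that list in these same values. Among 32 lists such a p can arise by chance, so it is no support for a difference, and the question stays open.

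The first component is high in 5 mice with neighbouring title numbers, 27 to 34, with a mean of 36.7 against -6.79 in the other mice. The 8 groups explained 25.2% of the component (permutation p = 0.371, over the bound of 0.2 set beforehand) and the 5 mice come from 5 of the 8 groups, which argues against age and sex as the whole source of the run, while a part of them stays open. For the order of handling, the mean of 5 mice in a row farthest from 0 had a permutation p of 0.00014, but this restates the pattern that prompted it and decides nothing on the order. A first version, run on the low end alone because the sign of the component had been turned, gave 0.469. The sets of title numbers explained 4.89%, the labels state no order or batch, and female juvenile replicate 3 (24.3, title number 43) and male juvenile replicate 2 (-73.1, title number 15) lie outside that run, so what sets these mice apart stays open.

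Chance could not be excluded for any count of probes at an unadjusted p under 0.05, by splits of the same mice. The real split is counted among the splits and among those that gave as many. For young adult versus juvenile 72 of 100 splits gave as many as the real 277 (highest other 5432), for old versus young adult 25 of 100 (1042, 6299), for middle-aged versus young adult 93 of 100 (86, 2187) and for old versus middle-aged 22 of 100 (1012, 4261). For the age slope it was 14 of 100 (1576, 4040), for adult females versus males 83 of 100 (199, 2350), for juvenile females versus males 9 of 35 (1730, 6966) and for adults minus juveniles 46 of 100 (757, 7017). For old minus young adult it was 100 of 100 (84, 2877), and for juveniles of 33 to 44 versus 17 to 21 days 29 of 56 (803, 6732). Other splits that called up to 3358, 3498 and 2967 probes after adjustment, in the comparisons of juvenile sex, of adults minus juveniles and within juveniles, point to a structure of the samples. For the lists, chance could not be excluded either: 5 of 100 splits gave a camera p as small as the real 9.52e-06 for the respiratory chain (smallest other 1.27e-07), 8 of 100 for fatty acid oxidation (0.00191, 5.54e-06) and 11 of 100 for ribosomal proteins (7.8e-07, 4.33e-14).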

How the results depend on the processing

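Alternatives added after the data were seen were the principal components, the 6 mice left out, the neighbouring probes, the pairs and, for lists, both scalings. The 0 calls of old versus young adult, the age slope, adult females versus males and the sex difference of old minus young adult held under every alternative run and every mouse left out. With arrayWeights, whose iterations stopped early, 2 probes passed in middle-aged versus young adult, 12 in old versus middle-aged, 949 between juvenile females and males, 14 in adults minus juveniles and 21 in juveniles of 33 to 44 versus 17 to 21 days. Without the juveniles of 17 to 21 days 1 probe passed in each of young adult versus juvenile, juvenile sex and adults minus juveniles, the same probe of Fbxl6 (it rests on 2 mice, female juvenile replicates 3 and 4). Leaving out a mouse gave 0 to 1 within juveniles, 1 (an unnamed probe) without female juvenile replicate 3. Of 62 named results 61 kept their sign throughout (not Gtf2h3, in the age slope with neighbouring probes subtracted), and 2651 of 2656 alternative values their side of the threshold. The others were Ski, Apc, Tmem147, Mettl6 and Irf8, called with arrayWeights. The named results were picked by smallest p in these same values, and most alternatives share nearly all mice, so kept signs are no independent support. No named result passed in the design set beforehand, so a kept side means only that it stayed uncalled. The median of all probes moved by at most 0.0566 under the scalings. Probes at an unadjusted p under 0.05 numbered, over the alternatives, 76 to 1576 in young adult versus juvenile (277 in the design set beforehand), 502 to 2072 in old versus young adult (1042), 12 to 1042 in middle-aged versus young adult (86), 556 to 3038 in old versus middle-aged (1012) and 494 to 3083 for the age slope (1576). They were 101 to 1561 in adult sex (199), 318 to 4610 in juvenile sex (1730), 311 to 2335 in adults minus juveniles (757), 23 to 333 in old minus young adult (84) and 415 to 2635 within juveniles (803). With scaling to the median absolute deviation the share above 0 went from 56.1 to 29.8% for the age slope, from 60.5 to 34.4% in juvenile sex, from 57.8 to 46.7% in adult sex, from 42.8 to 54.4% in adults minus juveniles and from 43 to 63% within juveniles. In middle-aged versus young adult this share went from 47.7 to 54.5%.

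For young adult versus juvenile the 2 lists became 0 with an estimated correlation, 0 with fry, 0 on membrane A alone, 0 without 6 mice whose arrays stand apart, 1 without juveniles of 17 to 21 days, 1 with the first 2 principal components, 1 with neighbouring probes subtracted and 1 with quantile normalisation. Leaving out a mouse gave 1 to 3. Fatty acid oxidation had an adjusted p of 0.572 without male juvenile replicate 2, 0.217 without female juvenile replicate 1, 0.236, 0.166, 0.0543 and 0.0651 without female young adult replicates 2 and 4 and male young adult replicates 3 and 5. Circadian genes passed without male young adult replicates 2 (0.0462) and 3 (0.047), female young adult replicate 3 (0.0196), female juvenile replicate 3 (0.0409) and male juvenile replicate 4 (0.0442), and with the title-number sets (0.0227). For old versus young adult the lists were 0 to 1 over mice left out, 1 without male old replicate 2. For adult sex the 1 list became 0 with an estimated correlation, 0 with fry, 0 without the 6 mice, 2 on membrane A alone and 2 with scaling to the median absolute deviation. Mice left out gave 1 to 6: 6 without male old replicate 4, 4 without female young adult replicate 1 or female middle-aged replicate 1, and 2 without male young adult replicate 2 or 3, female middle-aged replicate 2, female old replicate 3 or male middle-aged replicate 3. Of the 22 calls of further lists in adult sex, 6 in young adult versus juvenile and 1 in old versus young adult, 0 were kept by camera with an estimated correlation in the same setting, a test added after these were seen. Where fewer genes or mice were used, that lowers what a test can call; otherwise the cause was not tested. No paired analysis was possible by replicate number because these only name mice in the order of the records. By title number and age, 5 pairs of an adult male and female can be formed, which the labels do not call pairs; their deviations from the group means had r = 0.194 to 0.729 (median 0.0115 in other male and female adults), and 5 of the 10 mice correlated best with their partner. With the pairs as a block 0 probes and 3 lists passed (ribosomal proteins, acute phase and fatty acid oxidation), and the same 10 mice without a block gave 0 and the same 3, so the block changed no call. The offset before a log was not run, since the values are not linear.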

Other observations

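These values were picked after they were seen. With arrayWeights, whose iterations stopped early, Gstp1, a glutathione transferase, was 1 of 14 probes called for the sex difference of adults minus juveniles, at 1.40 ± 0.233 array SD (SE, adjusted p = 0.00754), against 0.725 without weights (adjusted p = 0.687). S100a9, a calcium-binding protein of neutrophils, was 1 of 21 called within juveniles, at 0.655 ± 0.124 for 33 to 44 versus 17 to 21 days (adjusted p = 0.024), against 0.457 without weights (0.687). The S100a9 probe lay below the array mean in every mouse (-1.89 to -0.92).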
